A study of Felis catus with 70 samples.

How the data were processed

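The data were ChIP-seq peak lists of 3 histone marks and the DNA-binding protein CTCF from 7 tissues of adult male domestic shorthair cats. The tissues were heart left ventricle, kidney cortex, left lateral lobe of the liver, lung, jejunum of the small intestine, testis and thyroid. Each combination of tissue and target had 2 biological replicates, so each of the 4 targets had 14 libraries and 56 per-library lists were used. Per the labels, tissue was flash frozen within 30 min of collection and kept at -80 C, chromatin was sonicated to 100 to 300 bp, and libraries were read single-end at 100 bp. Total reads, the non-redundant fraction and the normalised strand cross-correlation (NSC, a ratio that rises with enrichment) were taken from the labels.

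The submitters' processing notes name Bowtie2 2.4.2, MACS2 2.2.5 and SICER 0.0.51 without giving each a role. Lists for H3K27ac, H3K4me3 and CTCF had the layout of narrow peaks with a summit, and lists for H3K27me3 were broad regions with a header. In the narrow lists, the deposited signal column was read as the ratio (fold enrichment) of each peak over the background of the peak caller. The deposited p column of the narrow lists was read as -log10 of the p-value of each peak, and its lowest value was between 2.00 and 2.23 in the 63 narrow lists. In the broad lists, per the file headers, each region had a read count in the ChIP and input libraries, a log2 fold change and a p-value. The highest p-value in a deposited broad list was 0.0497. The authors also deposited 21 lists of replicated peaks, 1 per tissue for H3K27ac, H3K4me3 and CTCF, and the sources used here do not state how these were made. For H3K27me3, bases covered in both libraries of a tissue were used in their place. The 14 input libraries enter only through their read totals in the labels and were otherwise not analysed here.

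The genome build of the peak lists was not given in the sources used here. The gene table used belongs to the assembly F.catus_Fca126_mat1.0. Its fit to the peaks was tested with the 20439 protein-coding genes on 19 chromosomes: 76.3% had a replicated H3K4me3 peak over a gene boundary, against 22.0% with the genes moved 10 kb to the left and 21.6% with the genes moved 10 kb to the right. The share was 59.7% to 84.3% per chromosome, and in 0 of 236 bins of 10 Mb with at least 20 genes did moved genes match more peaks. The table was therefore used to name genes, and the coordinates printed are those of peaks in the lists, counted from 1. The table gave no strand, so "near a gene boundary" means within 1 kb of either end of a gene, and a promoter peak means a peak there. Shares of peaks near a boundary used the summit of each narrow peak and the midpoint of each H3K27me3 region.

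Similarity of 2 libraries was the Jaccard index in bases, which is the number of bases covered in both divided by the number covered in either. The 7 same-tissue pairs were compared with the 84 different-tissue pairs by a one-sided permutation test with 100000 random pairings of the 14 libraries. A peak counted as found in 1 tissue only when it overlapped no peak of another tissue by at least 1 bp. Differences between targets, and between distal and promoter peaks, were tested by exact two-sided sign-flip permutation over the 7 tissues, which gives 128 sign patterns and a smallest p of 0.0156. Distal H3K27ac peaks lay over 1 kb from a gene boundary and overlapped no H3K4me3 peak of the tissue. H3K27ac cover of a gene was the number of bases under peaks in the gene body plus 5 kb on each side, as a share of the covered bases of the library when tissues were ranked. Marker lists were tested by all assignments of lists to tissues, one-sided. Restricted promoters and H3K27me3 at listed genes were tested by two-sided Fisher's exact tests. Marks at the same genes were compared through log2 odds ratios with 0.5 added to each cell, tested over tissues by exact sign flips. Peak numbers were related to quality values by Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples, and repeated without the 2 libraries farthest from the median. The share of peak bases on chromosome X was compared between the 2 testis libraries and the 12 others by an exact two-sided test over 91 splits, whose smallest p is 0.011. P values were adjusted by the Benjamini-Hochberg method within each family, and 0.05 was the threshold. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

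Lists of marker genes for the 7 tissues, and 9 other lists, were written from general knowledge before the data were examined. Of their 272 symbols, 266 matched the gene table. The symbols without a match were SERPINA1 and ASGR1 for liver, SFTPA1 for lung, CDX1 for small intestine, PRM1 for testis and SIX6 among developmental regulators. Genes named were chosen by a rule set before the data were examined. For each marker list, they were the 3 members with an H3K27ac promoter peak in the tissue and in the fewest others, and every member without a replicated H3K27ac peak in its tissue. For each tissue, the 3 genes with the most H3K27ac cover among those with a promoter peak in that tissue only were added. Of the developmental regulators, the 5 with H3K27me3 in the most libraries were named, with ties in alphabetical order, as were any in no library. Some genes that the rule names are not reported here. Genes outside the rule are said to be chosen after their values were seen.

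The functions were tested on simulated data. Lists of 4000 peaks with 25% planted in 1 tissue only returned 25%, and a planted Jaccard index of 0.6 returned 0.6. Of 1000 sign-flip tests on data with no difference, 5.1% gave p under 0.05, and of 1000 split tests 4.6% did. Of 200 correlations of unrelated values 3.0% did.

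Other choices tried were a window of 500 bp or 2.5 kb, the strongest 0.5 of each list, equal numbers of the strongest peaks, an overlap of 0.5 of the peak, lists of single libraries, replicated peaks that overlapped both libraries, leaving out 1 tissue at a time, 20 kb of flank or none, and all sequences in place of the chromosomes. Choices added after the data were examined are named in the closing section. A planned search for the CTCF motif needed genome sequence and was not run. Depth limits what a list holds: ChIP libraries had 35195763 to 326659496 reads and inputs 33117789 to 61439117, and a gene without a peak had no peak at the threshold of its list, which does not show that the mark was absent.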

Results

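Peak lists of H3K27ac, H3K4me3, H3K27me3 and CTCF were compared across 7 tissues of adult male cats, with 2 libraries per tissue and target. H3K27ac marks active promoters and enhancers, H3K4me3 marks promoters, H3K27me3 marks genes repressed by Polycomb, and CTCF binds insulators and loop anchors. H3K27ac libraries had 37599079 to 76167951 reads and 63759 to 146498 peaks. H3K4me3 libraries had 43328327 to 74556768 reads and 30694 to 95452 peaks. CTCF libraries had 39806784 to 93410091 reads and 38806 to 113393 peaks. H3K27me3 libraries had 35195763 to 326659496 reads and 199 to 41311 regions, and heart replicate 1 held the lowest number. The replicated lists held 35524 to 81603 peaks per tissue for H3K27ac, 27505 to 50734 for H3K4me3 and 44457 to 70079 for CTCF. The share of replicated peaks that overlapped a peak of both libraries was lowest for CTCF in lung (47.6%) and liver (52.4%), and highest for H3K4me3 in lung (93.8%).

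The first comparison asked whether the cats' active chromatin separated by organ. Maps of H3K27ac from the same organ resembled each other more than maps from different organs, and each of the 14 H3K27ac libraries was closest to the other library of its own tissue. H3K4me3 separated organs too, for 12 of 14 libraries. CTCF and H3K27me3 lists did not separate them. For H3K27ac, the Jaccard index was 0.521 ± 0.0682 (SD, n = 7 pairs) within tissues and 0.313 ± 0.0613 (SD, n = 84 pairs) between tissues (one-sided permutation p = 2.0e-05, adjusted 4.0e-05 over 4 targets). H3K4me3 gave 0.665 ± 0.0891 (SD, n = 7 pairs) within and 0.515 ± 0.0968 (SD, n = 84 pairs) between tissues (permutation p = 2.0e-05, adjusted 4.0e-05). Testis was the most distant organ in H3K4me3, with mean indexes of 0.356 with liver to 0.416 with lung. Lung and thyroid were the closest pair of organs in H3K4me3, at 0.688 ± 0.0144 (SD, n = 4 library pairs). CTCF gave 0.378 ± 0.148 (SD, n = 7 pairs) within and 0.373 ± 0.104 (SD, n = 84 pairs) between tissues (permutation p = 0.401, adjusted 0.535), and 4 of 14 libraries were closest to their own tissue. H3K27me3 gave 0.168 ± 0.0946 (SD, n = 7 pairs) within and 0.205 ± 0.116 (SD, n = 84 pairs) between tissues (permutation p = 0.905), and 0 of 14 libraries were closest to their own tissue. The CTCF libraries of liver (0.202) and lung (0.221) overlapped least within a tissue.

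**Figure D1:**
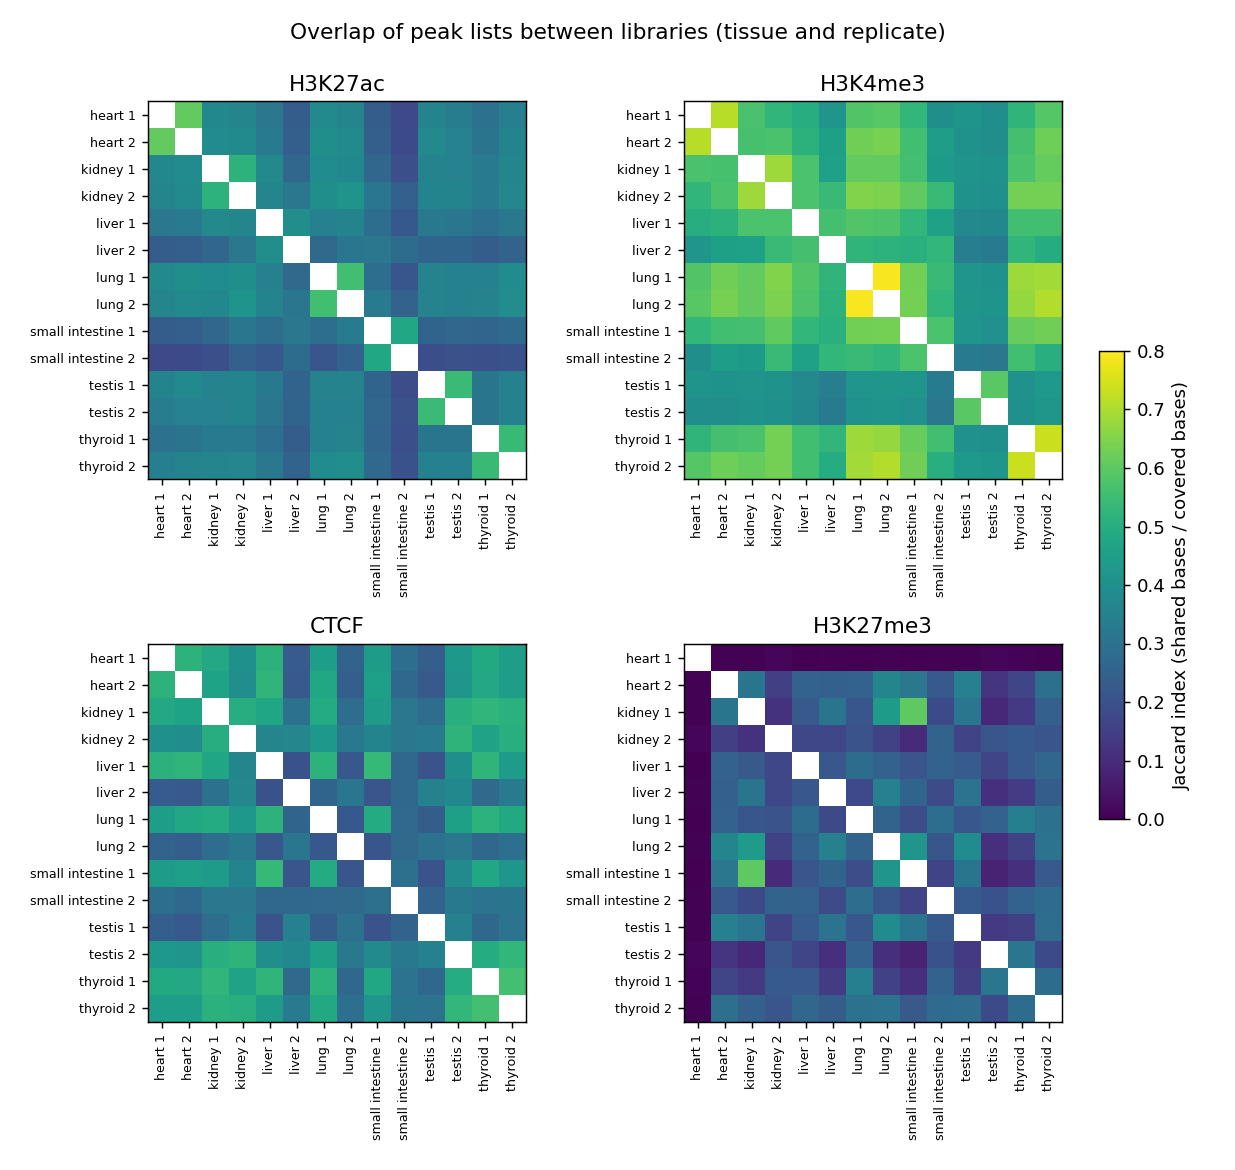
Jaccard index in bases (colour, 0 to 0.8) between each 2 of the 14 libraries, with 1 panel per target and libraries ordered by tissue and replicate on both axes. For H3K27ac the same-tissue pairs had a mean of 0.521 and the different-tissue pairs 0.313.

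The next question was how far each mark is confined to single organs. In the replicated lists, H3K27ac peaks were more often found in 1 organ only than CTCF sites were. In H3K4me3, testis had the longest list (50683 peaks) and the highest share found in no other tissue (46.4%), followed by heart (26.4%), with 4.04% to 14.4% elsewhere. With the strongest 13746 H3K4me3 peaks of each tissue, the share was 8.66% in testis and 0.655% to 5.72% elsewhere. On average, 21.4% ± 5.04 (SD, n = 7 tissues) of H3K27ac peaks, 16.9% ± 14.8 (SD, n = 7) of H3K4me3 peaks, 7.67% ± 4.99 (SD, n = 7) of CTCF peaks and 21.9% ± 8.11 (SD, n = 7) of H3K27me3 regions were found in 1 tissue only. The H3K27ac share was above the CTCF share by 13.8 percentage points, in 7 of 7 tissues (exact two-sided sign-flip p = 0.0156, the smallest possible; adjusted 0.0469 over 6 pairs). CTCF was below H3K27me3 in 7 of 7 tissues, with a difference of -14.2 points (exact p = 0.0156, adjusted 0.0469). The share of each tissue depends on the lists of the other tissues. The 7 values are thus not independent of each other, which the test does not take into account. The other 4 pairs of targets did not pass in the full lists, with adjusted exact p from 0.219 to 0.906. With equal numbers of the strongest peaks in each tissue, H3K27ac exceeded H3K4me3 by 10.4 points (adjusted exact p = 0.0234, n = 7). Those numbers were 17755 for H3K27ac and 13746 for H3K4me3, so they were equal between tissues but not between these targets. With lists of single libraries, the difference between H3K27ac and CTCF was 4.53 to 7.00 points and did not pass, and that between CTCF and H3K27me3 changed sign (2.58 to 7.46). Without heart, whose H3K27me3 list held 103 regions, the differences were 16.4 and -12.6 points, each at the smallest raw p that 6 tissues allow (exact p = 0.0312, adjusted 0.0938). Of all CTCF regions, merged over the tissues, 33.0% were present in all 7 tissues, compared with 21.2% of H3K4me3 regions and 8.36% of H3K27ac regions. For H3K27me3, with its short heart list, it was 0.0342%. Present in 1 tissue only were 33.6% of CTCF, 59.2% of H3K4me3, 59.7% of H3K27ac and 54.3% of H3K27me3 regions. A shared region counts once here but once per tissue among peaks, so these shares exceed those of peaks.

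**Figure D2:**
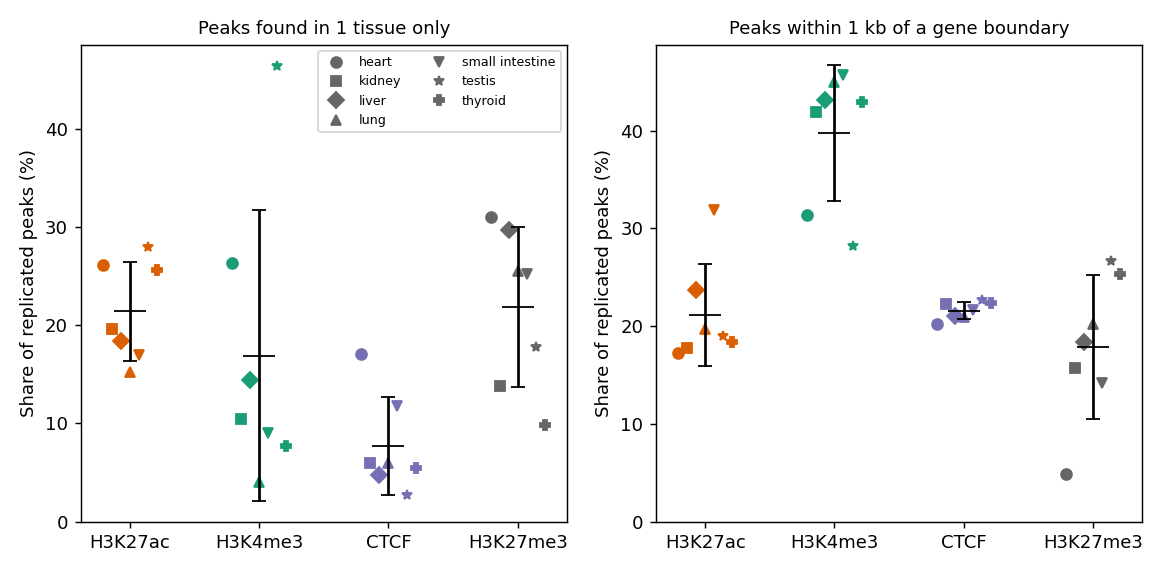
Percentage of replicated peaks found in 1 tissue only (left) and within 1 kb of a gene boundary (right), per tissue (symbols) and target, with the mean and SD of 7 tissues in black. The testis value for H3K4me3 (46.4% in 1 tissue only) was the highest of all tissues and targets.

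The marks also differed in how close to genes they lay. H3K4me3, the promoter mark, lay nearest. Within 1 kb of a gene boundary were 39.7% ± 6.97 (SD, n = 7 tissues) of H3K4me3 peaks, 21.6% ± 0.896 (SD, n = 7) of CTCF peaks, 21.1% ± 5.22 (SD, n = 7) of H3K27ac peaks and 17.9% ± 7.37 (SD, n = 7) of H3K27me3 regions. H3K4me3 exceeded H3K27ac, CTCF and H3K27me3 in 7 of 7 tissues (exact two-sided sign-flip p = 0.0156, adjusted 0.0312 for each). Distance was taken from the summit of narrow peaks but from the midpoint of H3K27me3 regions, whose median width per tissue was 2399 to 3799 bp. A broad region over a gene end could thus count as not near it, so the H3K27me3 share is not measured alike. The difference from H3K27me3 no longer passed with a window of 2.5 kb (adjusted exact p = 0.0625, n = 7), and without heart the 3 differences were -19.4 (H3K27ac minus H3K4me3), 19.3 and 21.1 points, each at the smallest raw p that 6 tissues allow (exact p = 0.0312, adjusted 0.0625). The difference between H3K27ac and CTCF did not pass in the full lists (exact p = 0.844, n = 7), but among the strongest 0.5 of each list 35.0% of H3K27ac and 16.3% of CTCF peaks lay near a boundary (adjusted exact p = 0.0234, n = 7). With lists of replicate 1 alone the difference was in the opposite direction, at -4.51 points (adjusted exact p = 0.0469, n = 7).

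Enhancers are held to be more organ-specific than promoters, and H3K27ac peaks were divided accordingly. Distal H3K27ac peaks were found in 1 organ only far more often than promoter peaks, in each of the 7 tissues. The shares were 30.9% ± 6.15 (SD, n = 7 tissues) for distal and 4.74% ± 3.77 (SD, n = 7) for promoter peaks, a difference of 26.2 points (exact two-sided sign-flip p = 0.0156, the smallest possible). Here too the share of each tissue depends on the lists of the others, which the test does not take into account. Heart had the highest distal share (40.1%) and lung the lowest (22.5%). Testis had the highest promoter share (13.1%), and small intestine the lowest (2.08%).

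Genes known for the work of each organ carried the most H3K27ac in that organ. Of 131 marker genes, 103 (78.6%) had their highest H3K27ac cover in the tissue of their list. Testis genes followed their tissue most closely (18 of 19), then liver (16 of 18), kidney (17 of 20), heart (16 of 20) and small intestine (15 of 19). Thyroid (10 of 16) and lung genes (11 of 19) did so least. The best of the other assignments of lists to tissues reached 64.1%, chance gives 14.3%, and the exact one-sided p over all assignments was 1.98e-04, the smallest possible.

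**Figure D3:**
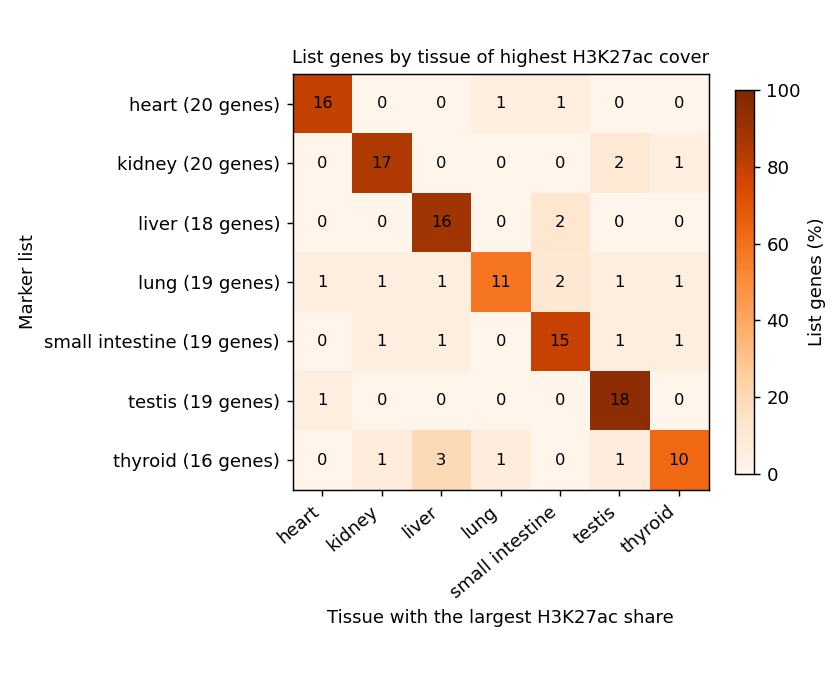
Marker genes of each list (vertical axis) by the tissue in which their H3K27ac cover was highest (horizontal axis), as gene counts, with the percentage of each list as colour. Counts on the diagonal sum to 103 of 131 genes.

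In heart, the muscle gene CSRP3, the ventricular light chain MYL2 and the myosin heavy chain MYH7 led the list. H3K27ac covered 12.5 ± 1.48 kb (SD, n = 2) at CSRP3 and 9.58 ± 2.31 kb (SD, n = 2) at MYL2, and both had promoter peaks in heart only for H3K27ac and H3K4me3. MYH7 had 20.9 ± 4.88 kb (SD, n = 2) in heart and 2.45 ± 0.0926 kb (SD, n = 2) in thyroid, with its widest heart peak on chromosome B3 from 73886529 to 73906051. In kidney, UMOD encodes the urinary protein uromodulin and SLC22A6 an anion transporter of the proximal tubule. UMOD had 7.09 ± 2.70 kb (SD, n = 2) and SLC22A6 had 5.08 ± 3.0 kb (SD, n = 2). CUBN, the tubular receptor cubilin, had 19.1 ± 8.21 kb in kidney (SD, n = 2). Heart (13.1 ± 0.00141 kb), lung (13.1 ± 4.17 kb) and thyroid (11.2 ± 6.66 kb; SD, n = 2 each) lay below the kidney mean by less than the kidney SD. CUBN had an H3K4me3 promoter peak in lung only. In liver, the clotting factor gene F9 had 12.2 ± 1.81 kb (SD, n = 2), the plasma protein gene AHSG 9.18 ± 1.99 kb (SD, n = 2) and the urea-cycle gene CPS1 7.31 ± 3.25 kb (SD, n = 2). These 3 genes had promoter peaks of both marks in liver only.

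In lung, CLDN18, a tight-junction gene of the alveolar epithelium, had 13.2 ± 4.31 kb (SD, n = 2), and the surfactant genes SFTPB and SFTPD had 9.68 ± 0.202 kb and 6.31 ± 2.05 kb (SD, n = 2). Each of these lung genes also had an H3K27ac promoter peak in thyroid. In small intestine, the intestinal transcription factor genes CDX2 and ISX had 9.31 ± 2.66 kb and 6.66 ± 0.566 kb (SD, n = 2), and the epithelial keratin gene KRT20 had 6.47 ± 0.250 kb (SD, n = 2). CDX2 had H3K4me3 at its promoter in all 7 tissues and H3K27ac there in small intestine only. In testis, DMRT1, a regulator of male germ cells and Sertoli cells, had 12.4 ± 2.79 kb (SD, n = 2). The sperm chromatin genes PRM2 and TNP2 had 6.77 ± 1.85 kb and 3.73 ± 0.639 kb (SD, n = 2), on chromosome E3. In thyroid, FOXE1, a thyroid transcription factor gene, had 11.7 ± 0.374 kb (SD, n = 2). NKX2-1, which directs both thyroid and lung epithelium, had 13.2 ± 0.423 kb in thyroid and 13.3 ± 0.0820 kb in lung (SD, n = 2 each).

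Some well-known markers had no replicated H3K27ac peak in their organ. These were the natriuretic peptide genes NPPA and NPPB in heart, CALB1 in kidney, SCGB3A2 in lung, and MUC2, LGR5 and CCK in small intestine. In thyroid they were SLC26A4, CALCA and the deiodinase gene DIO1. NPPA, NPPB and SCGB3A2 had no H3K27ac peak in any of the 14 libraries, although NPPB had H3K4me3 promoter peaks in 4 tissues, heart among them. DIO1 carried 11.2 ± 5.59 kb in liver and 8.60 ± 3.21 kb in kidney (SD, n = 2 each). CALCA, expressed in the C cells of the thyroid, had H3K4me3 there and in no other tissue.

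Promoter peaks found in a single organ were mostly those of testis, which also had the most genes with such a peak of each mark. Those genes numbered 15333 for H3K27ac and 15661 for H3K4me3, against at most 14121 and 14779 elsewhere. A peak at either gene end counted, and the part played by list length was not tested here. H3K27ac promoter peaks were present at 16751 genes, in all 7 tissues at 11251 of them and in 1 tissue at 1670, of which 934 were in testis. H3K4me3 promoter peaks were present at 16810 genes, in all 7 tissues at 13459 and in 1 tissue at 1613, of which 1069 were in testis. Marker genes were over-represented among the promoters restricted to their own tissue in 12 of 14 two-sided Fisher's exact tests after adjustment. Liver genes had the smallest p, with 10 of 17 restricted in H3K27ac (adjusted p = 1.8e-16) and 11 of 18 in H3K4me3 (Fisher's exact test, adjusted p = 9.5e-19). Of the testis genes, 12 of 16 were restricted in H3K27ac (Fisher's exact test, adjusted p = 4.4e-12). In H3K27ac, 0 of 18 lung genes and 0 of 12 thyroid genes were restricted to their tissue, and these were the 2 tests that did not pass.

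Genes with an H3K27ac promoter peak in 1 tissue only were ranked by the bases under H3K27ac peaks, and genes among the first 3 of each tissue are given. Heart had PDE3A, a cardiac phosphodiesterase gene (47.2 ± 9.65 kb, SD, n = 2), MEF2C, a muscle transcription factor gene (40.2 ± 7.05 kb, SD, n = 2), and PALLD. Kidney had ACSM5 (33.4 ± 13.3 kb, SD, n = 2), CLDN10 and FAM167A. Liver had CRADD and BCL6. Lung had TBX5, a lung and heart transcription factor gene (38.8 ± 19.3 kb in lung and 15.3 ± 0.0339 kb in heart, SD, n = 2 each), PALM2AKAP2 and HTR4. Small intestine had BAIAP2L2 (10.6 ± 1.17 kb, SD, n = 2), MBP and CDX2. Testis had MYLK, SLC14A2 and SRGAP2, and thyroid had SRPK2 (56.4 ± 12.7 kb, SD, n = 2), SHROOM3 and RAP1GAP2. Cover over the whole gene did not follow the promoter for PALLD, FAM167A, CRADD, PALM2AKAP2, MBP, MYLK, SLC14A2 and SRGAP2, whose cover, as a share of all covered bases, was highest in another tissue. MBP, for example, had 22.5 ± 8.11 kb in kidney and 9.58 ± 3.26 kb in small intestine (SD, n = 2 each). All H3K27ac peaks together covered 103.5 and 68.3 Mb in the kidney libraries and 44.5 and 33.3 Mb in those of small intestine. The gap in kb therefore overstates the gap in share. A peak at either gene end counted as a promoter peak, so some of these may not lie at a promoter. PDE3A, ACSM5, CRADD and MYLK had no H3K4me3 promoter peak in any tissue. FAM167A, BCL6, PALM2AKAP2, SRPK2 and SHROOM3 had none in the tissue they are given for.

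Lists of other cell types showed which other cells' genes were marked in the organ pieces. Immune genes were marked most often in thyroid: 12 of 12 had an H3K27ac promoter peak there, against 11 in lung, 9 in liver, 8 in small intestine and testis, and 7 in heart and kidney. Chosen after their values were seen, the leukocyte gene PTPRC had 19.7 ± 11.3 kb in thyroid and 4.68 ± 2.20 kb in lung (SD, n = 2 each). The T-cell genes CD3E, CD2 and CD8A had 10.8 ± 3.92 kb, 14.6 ± 2.02 kb and 12.8 ± 2.46 kb in thyroid (SD, n = 2 each). Of the 3 parathyroid genes, 3 had an H3K27ac promoter peak in thyroid and 1 to 2 elsewhere, while for H3K4me3 the count was 2 in thyroid and 3 in heart, kidney and testis. GCM2, the regulator of the parathyroid gland, had H3K27ac in thyroid alone, at 1.88 ± 2.66 kb (SD, n = 2). With a spread so far above the mean, nearly all of it lay in 1 of the 2 thyroid libraries. Endothelial genes had H3K27ac promoter peaks for 10 of 10 genes in lung and testis and 4 of 10 in small intestine. For H3K4me3 the counts were 10 in lung, 7 in testis and 9 in small intestine. Small intestine had the fewest genes with an H3K27ac promoter peak, 12066 against 13268 to 15333 elsewhere. H3K27ac promoter peaks were at 5 of 8 (liver and small intestine) to 8 of 8 (heart, lung and testis) fibroblast genes. They were at 5 of 8 (thyroid) to 8 of 8 (testis) smooth muscle genes. For skeletal muscle genes the H3K27ac counts were 2 of 10 (small intestine) to 6 of 10 (heart), and for adipocyte genes 2 to 3 of 5. All 20 housekeeping genes had promoter peaks of H3K27ac and H3K4me3 in all 7 tissues. These counts were not tested.

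Genes that lay down the body plan were covered by H3K27me3 in nearly all libraries. In the 13 libraries other than heart replicate 1, 45 to 59 of 59 developmental regulators carried it at a gene boundary, and 43 of the genes did so in all 13. ATOH1, BARHL2, DLX1, DLX2 and DLX5, transcription factor genes of nervous system and limb development, were among those 43. SHH, a signalling gene, carried it in 6 libraries and HOXA3 in 7, both chosen after their values were seen. The shares were 94.8% ± 7.31 (SD, n = 13 libraries) of developmental regulators and 17.3% ± 8.54 (SD, n = 13) of other genes, with odds ratios from 38.8 to 808. Each of the 13 libraries passed a two-sided Fisher's exact test (largest adjusted p = 9.2e-26). Neighbouring genes of the list, such as the HOXD genes, are not independent of each other, which the test does not take into account. Heart replicate 1, with 199 regions, covered 0 of 59 genes. Of 20 housekeeping genes, 0 were covered in 13 libraries and 1 in liver replicate 2, and 2 of 14 libraries passed the two-sided Fisher's exact test for a share different from that of other genes, kidney replicate 1 (adjusted p = 0.00352) and small intestine replicate 1 (adjusted p = 0.00333).

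**Figure D4:**
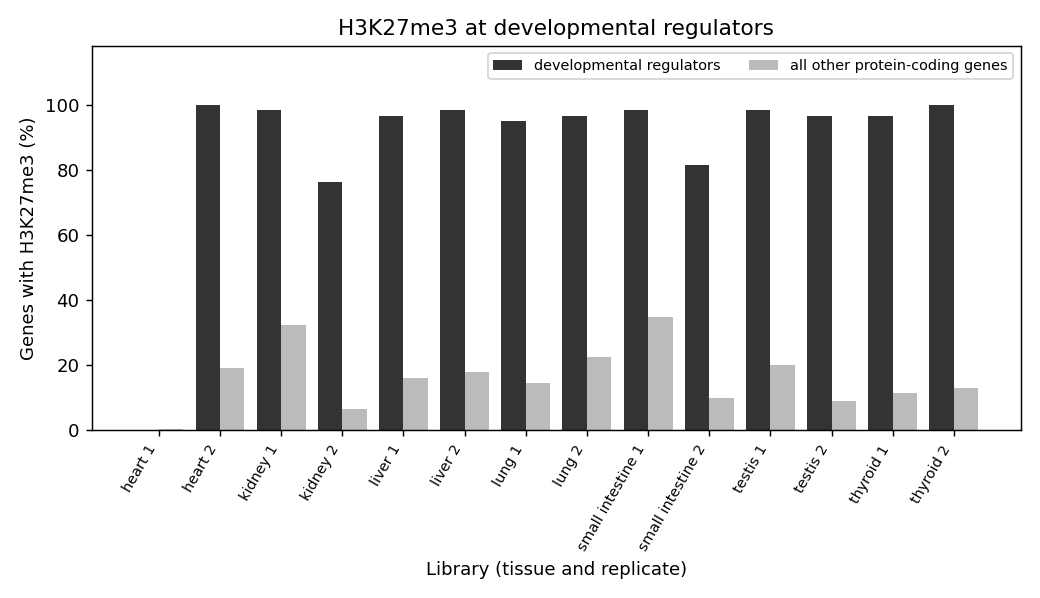
Percentage of genes with H3K27me3 at a gene boundary per library (bars), for developmental regulators and all other protein-coding genes. Heart replicate 1, with 199 regions, covered 0 of the 59 regulators, and the other 13 libraries covered 45 to 59.

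Active and repressive marks were then compared at the same genes. H3K27ac and H3K4me3 promoter peaks went together in every tissue, and in the replicated lists genes with H3K27me3 had H3K27ac less often in every tissue except testis. In testis, 79.1% of H3K27me3 genes had H3K27ac, against 74.5% of other genes, and 95.1% had H3K4me3. Of the developmental regulators, 36 of 59 had an H3K27ac promoter peak in testis, against 2 (small intestine) to 17 (kidney) elsewhere. This count was not tested, and testis had the most genes with such a peak, 15333 against 12066 to 14121 elsewhere. EN1 and EN2, chosen after their values were seen, carried H3K27me3 in 13 libraries and H3K27ac at the promoter in testis only. The log2 odds ratio of H3K27ac with H3K4me3 was 6.93 ± 0.22 (SD, n = 7 tissues), above 0 in 7 of 7 (exact two-sided sign-flip p = 0.0156, adjusted 0.0469). For H3K27me3 with H3K27ac it was -1.45 ± 1.09 (SD, n = 7), below 0 in 6 of 7 tissues and 0.37 in testis (exact p = 0.0312, adjusted 0.0469). From replicate 1 lists alone the mean was -0.68, with -0.12 in testis and 0.32 in kidney, and from replicate 2 lists it was -1.08, with 0.58 in testis. For H3K27me3 with H3K4me3 it was 0.87 ± 1.48 (SD, n = 7), above 0 in 6 of 7 tissues, which did not pass (exact p = 0.188). With lists of replicate 2 alone (0.67, adjusted exact p = 0.0312) or replicate 1 alone (0.75, adjusted exact p = 0.0469) it passed. Heart, with 27 genes in its H3K27me3 list, was the tissue below 0, at -2.12, and without it the mean was 1.36 (adjusted exact p = 0.0469, n = 6). Without heart, the mean for H3K27me3 with H3K27ac was -1.17 and did not pass (adjusted exact p = 0.0625, n = 6).

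Chromosome X is silenced in male germ cells during meiosis, so its share of peak bases was compared between testis and other organs. H3K4me3 peaks on X took a lower share in testis. The share was 1.78% ± 0.106 (SD, n = 2 libraries) in testis and 2.58% ± 0.291 (SD, n = 12) elsewhere, a ratio of 0.692 (exact two-sided p = 0.011, the smallest of 91 splits; adjusted 0.044 over 4 targets). Both testis libraries (1.71% and 1.86%) lay below the lowest of the others (1.95%). H3K27ac (1.54% and 1.62%; exact p = 0.681) and CTCF (1.24% and 1.65%; exact p = 0.231) gave no difference that passed, testis being named first. Neither did H3K27me3 (0.886% and 1.06%; exact p = 0.989), but heart replicate 1, at 6.51%, raised the mean of the others. Without heart replicate 1 the other tissues had 0.567% ± 0.156 (SD, n = 11), below the testis mean, in a comparison made after the data were seen that did not pass (exact p = 0.0256 over 78 splits, adjusted 0.0513 over 4 targets). Libraries of 1 tissue are not independent of each other, which this test does not take into account.

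**Figure D5:**
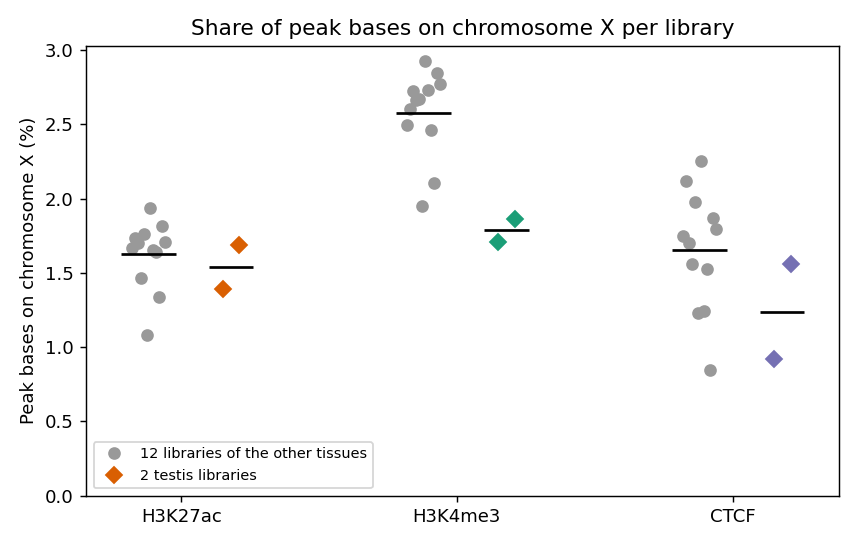
Percentage of peak bases on chromosome X per library, for testis (coloured) and the other tissues (grey), for H3K27ac, H3K4me3 and CTCF, with means as lines. For H3K4me3 the testis libraries (1.71% and 1.86%) lay below the lowest of the others (1.95%).

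Differences in enrichment between libraries were related to how many CTCF and H3K27me3 peaks were found. Across 14 CTCF libraries, peak number correlated with NSC at Pearson r = 0.695 (permutation p = 0.00564, adjusted 0.0338 over 12 relations) and Spearman rho = 0.811 (permutation p = 7.1e-04). Across 14 H3K27me3 libraries r was 0.738 (permutation p = 2.0e-05, adjusted 2.4e-04) and rho 0.837 (permutation p = 3.3e-04). Without the 2 libraries farthest from the median NSC, r was 0.829 for CTCF and 0.806 for H3K27me3. Within replicate number 1 and replicate number 2, r was 0.459 and 0.786 for CTCF, which did not pass, and 0.786 and 0.941 for H3K27me3. The other 10 relations, of H3K27ac and H3K4me3 peaks with NSC and of peaks of all 4 targets with total reads and the non-redundant fraction, did not pass. No difference in peak number between replicate 1 and replicate 2 passed after adjustment. The smallest p was for CTCF, with a log2 ratio of 0.43 ± 0.52 (SD, n = 7 tissues), higher in replicate 1 in 6 of 7 (exact two-sided sign-flip p = 0.0469, adjusted 0.188 over 4 targets).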

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

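Of the tests in this part, those of library enrichment, of H3K4me3 peaks shared with another tissue and of the gene end with H3K4me3 were chosen after the result was seen, and the strongest 0.5 of the H3K4me3 peaks, a setting planned before, was used as a test of weak peaks only after.

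The replicated lists held peaks on sequences outside the 19 chromosomes, which no comparison of the report uses. There were 131 such peaks for H3K27ac, 123 for H3K4me3 and 178 for CTCF over the 7 tissues, which is 0.0278%, 0.0525% and 0.0440% of the replicated peaks. They drew attention because they are signal in data left outside the comparisons. Testis held 51 of the H3K4me3 peaks and each other tissue 5 to 20. With all sequences included, the 4 similarity results kept their direction and side of the threshold.

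Lists of CTCF and H3K27me3 from 1 tissue were not closer to each other than lists from different tissues at a p that passed. Unequal enrichment may account for this, since peak numbers of both targets followed NSC. After the linear effect of the difference in NSC was removed from the Jaccard indexes, the excess within tissues was 0.0119 for CTCF (permutation p = 0.230) and -0.0374 for H3K27me3 (permutation p = 0.906). A first test, which removed 1 additive effect per library, was void by construction, since each library enters exactly 1 same-tissue pair, and it was replaced by this one. Unequal enrichment and shared CTCF sites across organs cannot be told apart here, because a linear correction may leave part of the effect of NSC in place, and the same holds for H3K27me3.

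The share of H3K4me3 bases on chromosome X was lower in testis. Weaker testis peaks at the threshold of the lists cannot be excluded. With the strongest 0.5 of each list the difference was still past the threshold (adjusted exact p = 0.044). The full testis lists held 95452 and 70146 peaks, against 30694 to 55023 elsewhere, and taking 0.5 of each keeps that imbalance. With only the peaks that overlap a replicated peak of another tissue, the share on X was 2.18% ± 0.109 (SD, n = 2) in testis and 2.66% ± 0.247 (SD, n = 12) elsewhere, a difference of -0.478 points (exact p = 0.044) where all peaks gave -0.794, and testis replicate 2 lay above the lowest of the others (2.26% and 2.13%). Dilution by autosomal peaks found in testis alone may account for part of the difference, but dilution and fewer X peaks, as silencing of X in germ cells would give, cannot be told apart, because the remaining difference lay between the bounds set for either. A first test, of regions present in all 6 other tissues, was saturated and is not used. Testis kept 97.7% of such regions on X and 97.7% on autosomes, and the other tissues kept 95.4% to 100% on X.

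H3K27me3 and H3K27ac were found at the same genes in testis more than in other organs. Opposite ends of a gene are argued against as the whole cause, because at the end with H3K4me3 the testis log2 odds ratio was 0.26, against -3.42 to -1.12 elsewhere. Depth of the H3K27me3 library of testis replicate 1 is argued against as well: replicate 2 lists alone gave 0.58, against -2.48 to -0.84 elsewhere, whereas replicate 1 lists gave -0.12 and put kidney above testis at 0.32. The value of 0.37 in the replicated lists could come from different cells of the testis, such as germ cells and somatic cells, or from both marks in the same cells. These cannot be told apart, because peak lists do not separate cells or alleles.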

How the results depend on the processing

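Chosen after seeing the data were leaving out heart (shares and marks), each tissue (replicate numbers) and heart replicate 1 (X share), the NSC correction, equal peak numbers without heart, peaks overlapping both libraries, and the gene end with H3K4me3. Of 338 recomputed values, 281 kept their direction and side of the threshold or moved by less than their spread, 31 changed sign, 12 no longer passed, 11 newly passed and 3 moved. Except where stated, the cause was not tested.

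Similarity of H3K27ac and H3K4me3 kept its calls under all alternatives. For H3K27me3 the excess within tissues was 0.0405 with equal numbers of strongest peaks, which heart replicate 1 limits to 77 per library, and -0.00237 with equal numbers and no heart. For CTCF it was -0.0117 (without heart) to 0.0276 (without liver), with 1 tissue left out. Leaving out a replicate could not be done, since each tissue then has no pair.

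For the share in 1 tissue only, equal numbers of strongest peaks gave 10.4 points for H3K27ac minus H3K4me3 and -26.4 for H3K4me3 minus H3K27me3, both past the threshold, and -0.256 for H3K4me3 minus CTCF. Numbers were equal between tissues and not between targets. Heart limits H3K27me3 to 51 regions, against 13746 H3K4me3 peaks, so the -26.4 says nothing about the targets. H3K27ac had 17755 peaks and CTCF 22211, so the 10.4 and the -0.256 do not compare targets at equal numbers either. Without 1 replicate, or without heart, H3K27ac minus CTCF was 4.53 to 16.4, H3K27ac minus H3K27me3 3.77 to 11.98, H3K4me3 minus H3K27me3 -2.63 to 9.24, and CTCF minus H3K27me3 -12.6 to 7.46. Calls lost without heart are due to the number of tissues, since 6 allow no raw p below 0.0312.

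For the share near a gene boundary, 500 bp gave 1.12 for H3K27ac minus CTCF and 5.72 for CTCF minus H3K27me3, which newly passed. A window of 2.5 kb gave -1.60 for H3K27ac minus H3K27me3 and 18.8 for H3K4me3 minus H3K27me3, which no longer passed. The strongest 0.5 of each list gave 18.6 for H3K27ac minus CTCF and 14.3 for H3K27ac minus H3K27me3, both past the threshold. It gave -4.31 for CTCF minus H3K27me3, which did not pass. Peaks overlapping both libraries gave 0.753 for H3K27ac minus CTCF. Without 1 replicate, or without heart, H3K27ac minus H3K4me3 was -19.4 to -16.0, H3K27ac minus CTCF -4.90 to -0.0777, H3K4me3 minus CTCF 11.1 to 19.3, H3K4me3 minus H3K27me3 18.4 to 21.1, and CTCF minus H3K27me3 1.75 to 8.93. The 3 differences of H3K4me3 no longer passed without heart, H3K27ac minus CTCF passed without replicate 2, and CTCF minus H3K27me3 passed without replicate 1.

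Distal against promoter H3K27ac, the marker lists, the count of restricted promoters and the count of libraries with H3K27me3 at developmental regulators kept their calls under all alternatives. Within 1 kb, 5 libraries passed for housekeeping genes. Without 1 replicate, or without heart, the log2 odds ratio was -1.17 to -0.68 for H3K27me3 with H3K27ac and 0.67 to 1.36 for H3K27me3 with H3K4me3. The first no longer passed without heart, and the second passed in each case.

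Of the relations of peak number with quality, 1 passed within replicate number 1 and 1 within replicate number 2. Without the 2 farthest libraries, r was 0.154 for H3K27ac with the non-redundant fraction and -0.213 for CTCF with reads. Within replicate number 1, r was -0.639 for H3K27ac with reads, 0.313 for H3K27ac and -0.113 for H3K4me3 with the non-redundant fraction, and -0.124 for CTCF with reads. Within replicate number 2, it was 0.125 for H3K4me3 with NSC and -0.835 for CTCF with reads. With 1 tissue left out, the log2 ratio of replicate 1 to replicate 2 was -0.0212 (without testis) to 0.12 for H3K4me3 and -0.93 to 0.65 (without heart) for H3K27me3. The X share of H3K27me3 in testis minus others was 0.122 points with the strongest 0.5 of each list and 0.319 without heart replicate 1.

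Deviations of same-numbered libraries correlated at -0.616 to 0.789 between tissues, leaving pairing by number open. In the replicate block, the share in 1 tissue only gave 5.76 for H3K27ac minus CTCF, which did not pass. It gave 10.8 for H3K27ac minus H3K27me3, 7.97 for H3K4me3 minus H3K27me3 and 5.02 for CTCF minus H3K27me3. The share near a boundary gave -4.70 for H3K27ac minus CTCF and 7.59 for CTCF minus H3K27me3. Sign flips here treat libraries of 1 tissue as independent, so passes are not given. Another 12 tested results kept their direction, and of 4 untested ratios of X share, that of H3K27me3 went from 0.834 to 1.04. The planned search for the CTCF motif and its alternatives were not run.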

Other observations

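The highest Jaccard index of any 2 H3K27me3 libraries was between different organs. Kidney replicate 1 and small intestine replicate 1 reached 0.601, with 162 Mb and 207 Mb covered. Their NSC values, 1.05 and 1.20, were the highest of the 14 H3K27me3 libraries. Testis replicate 1 of H3K27me3 had 326659496 reads, the most of the 56 ChIP libraries.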
